A study of Pan troglodytes and Pan paniscus and Gorilla gorilla with 3 samples.

How the data were processed

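One Hi-C library each of chimpanzee, bonobo and gorilla lymphocytes was analysed, each species forming a group of 1. Per the labels' protocols, cells were fixed with formaldehyde, cut with HindIII and ligated in dilution, the form of the assay in which ends are joined in a large volume after lysis. Per the submitters' processing notes, the maps were made with Juicer and refer to hg38; the Juicer version is not given in the sources used here. The names of the deposited tables carry an assembly of each species and the word mapping. Reads may therefore have been placed on each species' own genome before positions were expressed on hg38, but no label states this step, nor how positions were matched.

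Each table lists pairs of 50 kb bins and a value. No label states its scale. The deposited values were read as the natural log of 1 plus a contact value, a base chosen from the values and stated by no label: on chromosome 3, which is listed whole, the sums per bin of the back-transformed values had a CV of 3.58% to 5.34% with the natural base, against 7.81% to 8.65% with base 2, 11.9% to 12.6% for the values as deposited and over 35% with base 10. Even sums per bin are what balancing a map leaves, so the values are taken as balanced within the chromosome. The check covers chromosome 3 alone, and even sums need not hold elsewhere. In the bonobo bins on chromosome 6 described below, both near and distant contacts were low. Neighbouring pairs correlated at 0.889 or more even 50 Mb apart, which points to smoothing before deposit. The balancing method, the smoothing and the definition of the listed blocks are not given in the sources used here. Smoothing spreads a sharp change over neighbouring bins and takes away noise that would lower a correlation between maps. Read totals are unknown, so no counting interval is given.

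Values were transformed back to the linear contact value. The expected value is the mean over listed pairs at the same distance, per species and chromosome. Distance decay is the slope of log mean value on log distance from 500 kb to 5 Mb over pairs above 0 in all 3 species. Map similarity is the Pearson correlation of log2 observed over expected over pairs 100 kb to 2 Mb apart, per autosome. Insulation is log2 of the mean value in a 500 kb square across a bin over its chromosome mean, with at least 80% of the square listed. Boundaries are its local minima of prominence at least 0.2, shared within 1 bin, and sharing was set beside 100 circular shifts. Compartments are the first eigenvector of the correlation matrix of observed over expected in 250 kb bins, with the ratio limited to 5, per arm or contiguous block of at least 20 bins, scaled to an SD of 1 and oriented alike among species.

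Divergent blocks are 500 kb squares 1 to 10 Mb apart that differ by at least 1 on the log2 scale in the same direction from both other species, while those differ by under 0.5, with at least 50% of pairs above 0. Long-range contacts are 250 kb squares over 5 Mb apart at 10 or more times the expected value in 1 species and under 2 in at least 1 other. Cross-contact depletion is log2 observed over expected of contacts between the 2 Mb on each side of a position, with at least 50% of pairs listed. No test was made, as each species has 1 library, and autosomes are not replicates.

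Regions were named by a rule set before the data were examined: the 5 per species with the largest difference to the nearer of the other species, 2 Mb apart for divergent blocks and insulation and 5 Mb apart for long-range contacts and depletion. The text gives some of these in full and the others as counts. For depletion, the strongest were taken as the largest differences to the nearer species, with the lowest positions in all 3 species beside them, a reading chosen after the data were seen. The compartment stretches, the 3 slope differences between species as results, the low-signal rule, the limit on the ratio, the listed-share minimums and the 0.7 limit on segments were also chosen after the data were seen. A low-signal bin has a mean value with its 2 nearest neighbours on each side under 0.25 of the chromosome median, which held for 133 bins in chimpanzee, 274 in bonobo and 119 in gorilla. A bin low in any species was left out of all 3. Gene lists and marker genes planned at the start were not used here, since they need an hg38 annotation, and regions are given by coordinates alone.

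The code was tested on simulated maps of chromosomes 20 to 22, with an assumed noise that need not match the real libraries. Of planted block changes of 1.5 on the log2 scale, 94 of 100 were recovered, and of 2.5, 97 of 100, with 0 calls at the 3771 blocks left alone. The simulated copies differed only by that noise and the planted changes, with no bins low in 1 copy alone. The 0 calls therefore give no rate of false calls in the real maps. A planted depletion was found at its position, and 85 of 115 boundaries (73.9%) were found again within 1 bin. Noise of that size alone thus leaves some boundaries unmatched. Alternatives covered distance ranges, bin and window sizes, thresholds, zeros, scaling and low-signal bins. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.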

Results

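Chromosome contact maps were compared among 3 great apes: the chimpanzee, its sister species the bonobo, and the gorilla, whose lineage split off before those of the first pair. Each map came from 1 Hi-C library of a lymphocyte line grown in suspension, so there are no replicates, and no p-value is given. Hi-C joins DNA ends that lie close together in the nucleus and reads how often any 2 places in the genome met. All positions are on the human build hg38, per the submitters' processing notes, and how they were matched among species is not given in the sources used here. The spread given below is the SD over the 22 autosomes, which describes how a value varies along one genome and is not replication.

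Every species had a value for the same 30154205 pairs of 50 kb bins, which fall into 90 contiguous blocks with 47949 bins. A value of 0 stood at 51892 pairs (0.172%) in chimpanzee, 64132 pairs (0.213%) in bonobo and 44033 pairs (0.146%) in gorilla. Median natural log values were 0.732, 0.729 and 0.721 in the same order. Read totals are not given in the sources used here, so the depth behind each map is unknown. Some chromosomes were listed only in part. Chromosome 5 was listed from 80.65 to 180.1 Mb and chromosome 17 from 0.15 to 15.5 Mb, and these are the human counterparts of the chromosomes that exchanged arms in the gorilla lineage. Chromosome 2, formed in the human lineage by the fusion of 2 ape chromosomes, had no listed bin between 108.1 and 113.65 Mb.

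Contacts from 500 kb to 5 Mb apart fell most steeply in gorilla. Between 500 kb and 5 Mb the slope of log contact value on log distance was -1.22 (SD 0.0306) in gorilla, -1.13 (SD 0.0315) in chimpanzee and -1.10 (SD 0.0364) in bonobo. The gorilla slope was the steepest on 22 of 22 autosomes, and the chimpanzee slope was steeper than the bonobo slope on 22 of 22. The mean difference of chimpanzee minus gorilla was 0.0869 (SD 0.0257) and that of bonobo minus gorilla was 0.124 (SD 0.0241). At 100 kb the mean contact value was 24.4 times that at 2 Mb in gorilla, 20.3 times in chimpanzee and 17.2 times in bonobo. Chromosome 19 had the steepest chimpanzee and bonobo slopes, -1.21 and -1.16, beside -1.21 in gorilla. From 1 to 10 Mb the slopes lay closer together, at -1.03 in chimpanzee, -1.04 in bonobo and -1.05 in gorilla, with gorilla the steepest on 19 autosomes. The order of the other two species turned there: chimpanzee minus bonobo averaged 0.0108 (SD 0.0648), against -0.0371 from 500 kb to 5 Mb, and chimpanzee was the steeper on 12 of 22. Further out the order turned, over fewer pairs. At 50 Mb the mean contact value was 0.0934 of that at 2 Mb in gorilla, 0.0747 in chimpanzee and 0.0779 in bonobo. At 100 Mb these were 0.0294, 0.0275 and 0.0242, while at 20 Mb gorilla was still the lowest, at 0.168 beside 0.180 and 0.171. The means rest on 8848 pairs at 50 Mb and 3112 at 100 Mb, against 44245 at 2 Mb. Only listed blocks longer than a distance give pairs at it, so far and near values come from unlike sets of chromosomes. With 1 library per species, a difference between libraries cannot be separated from one between species.

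**Figure D1:**
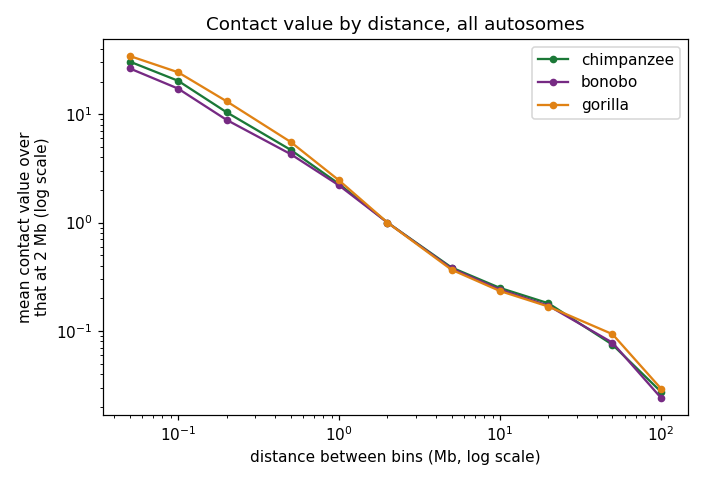
Mean contact value at 11 distances, divided by the value at 2 Mb, against the distance between bins in Mb, with both axes on a log scale and 1 line per species. Each point covers the autosomes with listed pairs at that distance, which are fewer at far distances. At 0.1 Mb the points stand at 24.4 in gorilla, 20.3 in chimpanzee and 17.2 in bonobo, and at 50 Mb at 0.0934, 0.0747 and 0.0779.

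The chimpanzee and bonobo maps were the most alike at short range. Over bin pairs 100 kb to 2 Mb apart, the correlation of log2 observed over expected contacts averaged 0.795 (SD 0.0996) for chimpanzee with bonobo, 0.733 (SD 0.0890) for chimpanzee with gorilla and 0.697 (SD 0.116) for bonobo with gorilla. The chimpanzee and bonobo pair had the highest correlation on 17 of 22 autosomes. On chromosome 8 it was 0.872, against 0.652 and 0.641 for the pairs with gorilla, and on chromosome 5 it reached 0.914 against 0.645 and 0.617, a gap that shrank without low-signal bins. On chromosome 6 the order broke: chimpanzee with gorilla stood at 0.820, chimpanzee with bonobo at 0.469 and bonobo with gorilla at 0.428, and this chromosome holds a stretch of bonobo bins with almost no contacts, described below. Chromosome 17, listed over its first part alone, was the 1 autosome where bonobo and gorilla were the closest pair, at 0.835.

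Bins with little signal in any species carried part of these differences. With such bins left out, an alternative chosen after seeing the data, the 3 correlations averaged 0.832, 0.780 and 0.783, and the chimpanzee and bonobo pair was the highest on 20 of 22 autosomes. Chromosome 8 then gave 0.856, 0.642 and 0.631 in the same order, and chromosome 5 gave 0.868, 0.827 and 0.807. Chromosome 6 gave 0.880 for chimpanzee with bonobo, 0.833 for chimpanzee with gorilla and 0.836 for bonobo with gorilla. Chromosome 2, where chimpanzee with gorilla was the highest at 0.832, and chromosome 17 were the exceptions. The lead faded with distance: over pairs 10 to 50 Mb apart, with all bins, the averages were 0.532, 0.526 and 0.535 on 21 autosomes, and chimpanzee with bonobo was the highest on 8 of them. With low-signal bins left out these averages were 0.535, 0.529 and 0.549. Chimpanzee with bonobo was then the highest on 7 and bonobo with gorilla on 11. Values of neighbouring pairs correlate strongly within each map, so the pairs are not independent measurements.

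**Figure D2:**
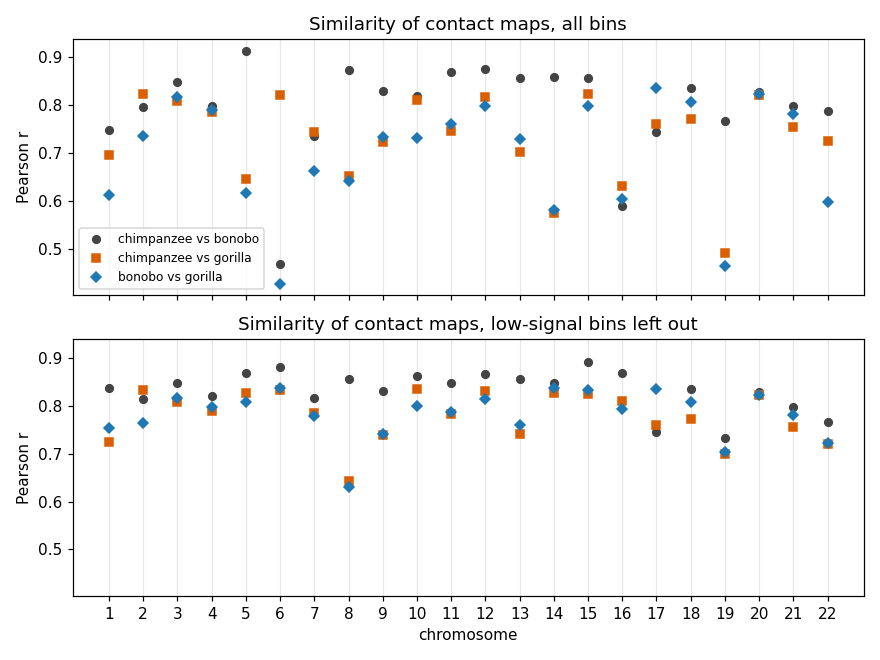
Pearson correlation between the contact maps of each pair of species (vertical axis, no unit) on each of the 22 autosomes, over bin pairs 100 kb to 2 Mb apart, with all bins above and low-signal bins left out below. Chromosome 6 rises from 0.469 to 0.880 for chimpanzee with bonobo, while chromosome 8 keeps both gorilla pairs under 0.66.

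Domain boundaries sat at the same places in most cases. A boundary is a dip in the contacts that cross a bin, and 2110 were called in chimpanzee, 2061 in bonobo and 2146 in gorilla. Of these, 80.8% were shared within 1 bin between chimpanzee and bonobo, 74.4% between chimpanzee and gorilla and 74.4% between bonobo and gorilla, against 13.7%, 14.1% and 13.8% after random circular shifts of the positions (highest of 100 shifts 16.9%). The insulation profiles correlated at 0.862 (SD 0.0980), 0.825 (SD 0.0394) and 0.791 (SD 0.0840), and chimpanzee with bonobo was the highest on 19 of 22 autosomes. Strong boundaries were shared more often, in part by construction, since a partner must itself reach a prominence of 0.2. Of chimpanzee boundaries with prominence from 0.2 to 0.4, 39.6% were found in all 3 species, rising to 68.3% from 0.4 to 0.8 and 79.8% from 0.8 up. Gorilla had the most boundaries of its own, 387 (18.0%), against 243 (11.5%) in chimpanzee and 207 (10.0%) in bonobo. A boundary in gorilla alone is the same pattern as one missing from chimpanzee and bonobo together, so this count does not place a change in gorilla.

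**Figure D3:**
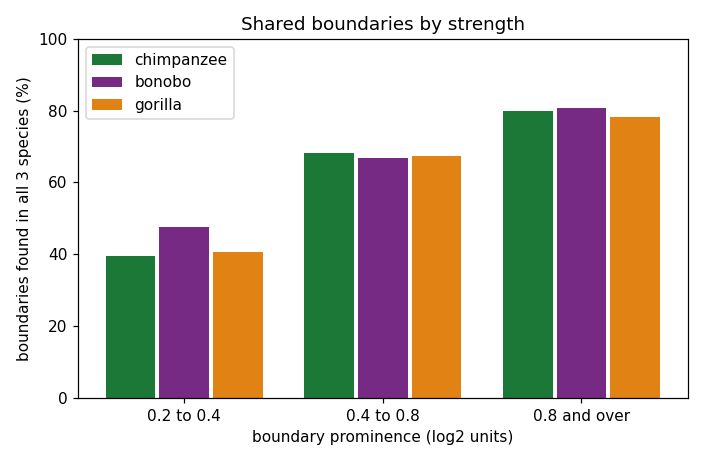
Share of each species' boundaries found in all 3 species, in percent from 0, by the prominence of the boundary in log2 units, with 1 bar per species. In the strongest class the bars stand at 79.8% in chimpanzee, 80.8% in bonobo and 78.2% in gorilla.

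Single positions differed far more than the profiles as a whole. On chromosome 8, gorilla insulation was -5.05 at 31.15 Mb, where chimpanzee had -0.75 and bonobo -0.63, and -4.89 at 84.95 Mb, where they had -0.15 and 0.07 (log2 of contacts across the bin over the chromosome mean). Of the 5 bonobo positions that stood furthest apart, the only one with no low-signal bin in the window was 121.65 Mb on chromosome 2. It stood at -3.83 beside -0.14 in chimpanzee and -0.05 in gorilla. The 5 chimpanzee positions that stood furthest apart all had low-signal bins in the window, as did 4 of 5 in bonobo and 3 of 5 in gorilla. The largest chimpanzee difference was at 18.75 Mb on chromosome 16, at -5.21 in chimpanzee, -2.11 in bonobo and -1.84 in gorilla.

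Large-scale compartments, the alternating active-like and inactive-like stretches of chromosomes, were similar in all 3 species on average over each autosome, though not in every segment. Compartment scores in 250 kb bins correlated at 0.894 (SD 0.0456) for chimpanzee with bonobo, 0.865 (SD 0.0742) for chimpanzee with gorilla and 0.887 (SD 0.0406) for bonobo with gorilla. Scores had opposite sign in 11.5%, 12.4% and 12.1% of 9383 bins, differences smaller than the SD over autosomes, which was 3.48, 4.51 and 2.77 percentage points. The first pair was the highest on 9 autosomes, the second on 4 and the last on 9. Without an annotation of hg38 the sign of a score carries no meaning here, and agreement alone is given.

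Some stretches of several bins changed sign in 1 species, named after their values were seen. On chromosome 3 from 75.75 to 77.75 Mb the mean score was -0.311 in chimpanzee, against 1.02 in bonobo and 1.11 in gorilla. On chromosome 4 from 22.75 to 24.5 Mb it was 0.823 in chimpanzee, -0.813 in bonobo and -0.714 in gorilla. Gorilla stood apart on chromosome 7 from 16.5 to 18 Mb, at 1.08 beside -0.680 in chimpanzee and -0.601 in bonobo, and on chromosome 13 from 45.25 to 46.5 Mb, at 0.873 beside -0.443 and -0.598. Bonobo stood apart on chromosome 2 from 149.5 to 151.25 Mb, at 0.459 beside -0.439 in chimpanzee and -1.08 in gorilla, a stretch that ends beside a depleted position described below. In 11 of 77 segments, with 485 bins, the lowest correlation between species was under 0.5, and in 6 of them under 0.3. It fell to -0.164 between chimpanzee and bonobo on chromosome 12 from 38.25 to 47.5 Mb and to 0.00611 between chimpanzee and gorilla on chromosome 6 from 158.25 to 170.5 Mb. Segments under 0.7, which are the same 11, were not used for naming stretches. Each score is the first eigenvector alone. Taking the better matching of the first 2, a choice that favours agreement, raised the 3 average correlations over autosomes to 0.902, 0.877 and 0.898. Whether the low segments differ in which eigenvector comes first was not tested.

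Contacts between separate 500 kb regions stood apart in 1 species at a small share of places. Of 73962 blocks 1 to 10 Mb apart, 471 (0.637%) differed from both other species by at least 1 on the log2 scale in chimpanzee, 922 (1.25%) in bonobo and 961 (1.30%) in gorilla. Most were lower: 286 of 471 in chimpanzee, 818 of 922 in bonobo and 664 of 961 in gorilla. Here too, gorilla apart is the same pattern as chimpanzee and bonobo apart together. With the expected value taken over all autosomes, the share of higher blocks in gorilla was 42.9% of 1285, against 30.9% of 961 with the expected value of each chromosome. By number, most bonobo blocks lay on chromosome 2, with 194, and most gorilla blocks on chromosome 1, with 131, which are the chromosomes with the most listed bins. Per 100 listed bins chromosome 22 had the most in both, 9.66 in bonobo and 6.15 in gorilla, against 4.32 on chromosome 2 and 3.07 on chromosome 1. Blocks within 2 Mb of an edge of the listed sequence made up 27.5% of all such blocks, and 13.9% of those tested.

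The gorilla blocks furthest from the others included chromosome 8, where contacts of 30.5 to 31 Mb with 31.5 to 32 Mb were -6.97 in gorilla, -1.05 in chimpanzee and -1.10 in bonobo. A further one on chromosome 8 joined 84 to 84.5 Mb with 85 to 85.5 Mb, at -4.75 in gorilla, -0.66 in chimpanzee and -0.49 in bonobo. On chromosome 12, contacts of 122.5 to 123 Mb with 128 to 128.5 Mb were -1.04 in chimpanzee, -4.16 in bonobo and -4.11 in gorilla, so that chimpanzee was the higher. On chromosome 8, contacts of 139.5 to 140 Mb with 143.5 to 144 Mb were -4.60 in chimpanzee, -1.16 in bonobo and -1.37 in gorilla. The largest bonobo difference, on chromosome 6 between 64.5 to 65 Mb and 65.5 to 66 Mb, was -8.31 beside 0.82 in chimpanzee and 0.76 in gorilla. Low-signal bins touched 4 of the 5 bonobo blocks that differed most, 3 of 5 in gorilla and 1 of 5 in chimpanzee. With these bins left out the counts were 461 in chimpanzee, 664 in bonobo and 821 in gorilla.

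Contacts over 5 Mb apart rarely reached 10 times the expected value in 1 species. Chimpanzee had 1 such place, on chromosome 3 between 12.75 to 13 Mb and 129 to 129.25 Mb, at 10.9 times beside 1.19 in bonobo and 3.39 in gorilla. Gorilla had 1, on chromosome 4 between 119.25 to 119.5 Mb and 128 to 128.25 Mb, at 10.1 times beside 1.30 in chimpanzee and 1.20 in bonobo. Bonobo had 0. At 5 times the counts were 416 in chimpanzee, 198 in bonobo and 121 in gorilla, of which 359, 128 and 97 lay on chromosome 3. That chromosome is listed as 1 block and has 7567995 of the 30154205 pairs, a smaller share than its share of these contacts. The chimpanzee place there spans 116.25 Mb. At 100 Mb the mean chimpanzee value was 0.197, against 7.15 at 2 Mb, so a small value can give a high ratio at such distances.

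Neighbouring sequence on hg38 made few contacts in 1 species at several positions, which can mark places where that genome is arranged differently. Contacts across 121.65 Mb on chromosome 2 were -3.20 in bonobo, 6.95 times below the nearer of the other two species, with -0.41 in chimpanzee and -0.30 in gorilla. A second bonobo position on chromosome 2, at 151.3 Mb, stood at -2.89 beside -0.46 in chimpanzee and -0.53 in gorilla, 5.17 times below the nearer. In gorilla the strongest of the positions that this scan could rank were 227.95 Mb on chromosome 1, at -2.66 beside -0.12 in chimpanzee and -0.26 in bonobo, and 239.95 Mb, at -2.11 beside -0.05 and 0.06. The scan needs 2 Mb of listed block on each side, so it gave no value at the gorilla insulation minima on chromosome 8, at 31.15 and 84.95 Mb. The next in gorilla was 32.35 Mb on chromosome 9, at -1.84 beside -0.73 and -0.80. Bins within 2 Mb of these positions had near-diagonal contacts close to the chromosome median, from 0.969 to 1.05 times it in the affected species on chromosomes 1 and 2. Low-signal gorilla bins within 2 Mb numbered 1 at 227.95 Mb and 2 at 239.95 Mb on chromosome 1.

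**Figure D4:**
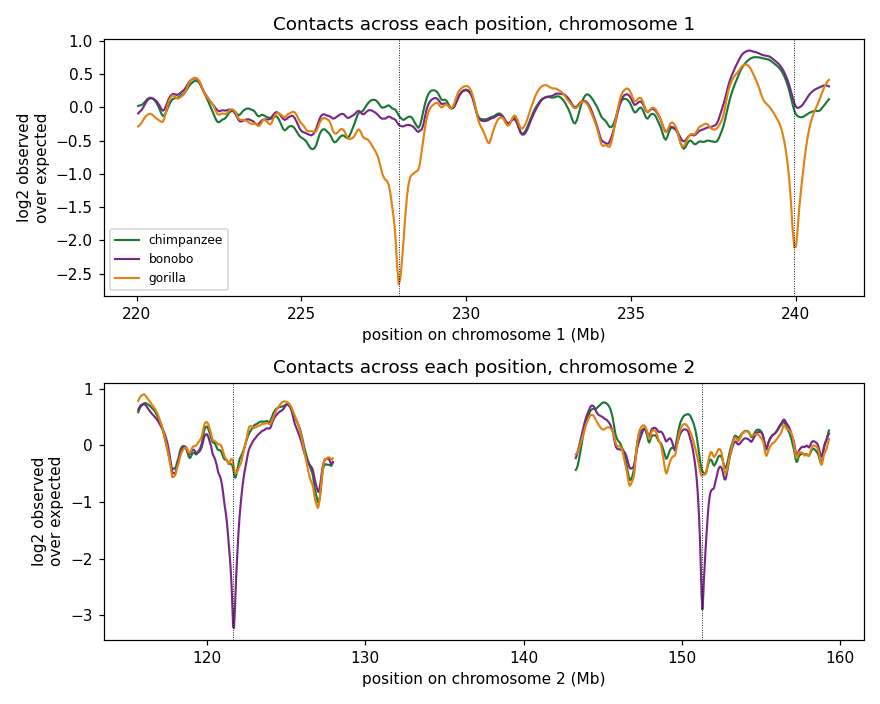
Contacts across each position, as log2 of observed over expected in 2 Mb windows on each side, against the position in Mb on chromosomes 1 and 2, with 1 line per species and dotted lines at the named positions. At the dotted lines the gorilla line stands at -2.66 and -2.11 on chromosome 1 and the bonobo line at -3.20 and -2.89 on chromosome 2, while the other species lie between -0.53 and 0.06.

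Chimpanzee showed no position as strong. Its lowest against the others was 128.4 Mb on chromosome 12, at -0.79 beside 0.51 in bonobo and 0.07 in gorilla. Of 40957 positions scanned, 0 in chimpanzee, 5 in bonobo and 3 in gorilla were lower than both other species by at least 1, at 5 Mb spacing. The remaining bonobo positions lay at 65.1 Mb on chromosome 6 and at 16.7 and 28.5 Mb on chromosome 16, with 31, 41 and 26 low-signal bonobo bins within 2 Mb. On chromosome 6 from 64.3 to 65.85 Mb, 31 bins in a row had a median near-diagonal contact of 0.00393 of the chromosome median in bonobo, against 0.727 in chimpanzee and 0.622 in gorilla. All 3 species were low together at 57.9 Mb on chromosome 12, at -1.71 in chimpanzee, -1.73 in bonobo and -1.80 in gorilla, and at 113.1 Mb on chromosome 1, at -1.58, -1.71 and -1.55.

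**Figure D5:**
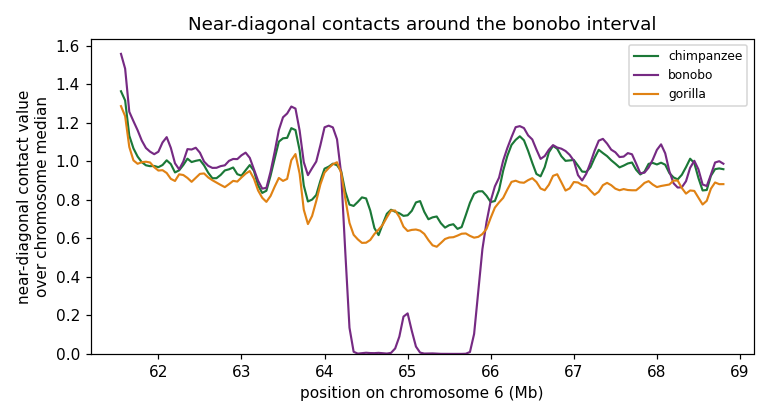
Near-diagonal contact value of each 50 kb bin divided by the chromosome median, against the position on chromosome 6 in Mb, with 1 line per species. From 64.3 to 65.85 Mb the bonobo median is 0.00393, against 0.727 in chimpanzee and 0.622 in gorilla. Within this stretch the bonobo line rises to 0.210 at 65 Mb.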

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

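No paired analysis was possible because each species has 1 library, and leaving out a replicate was not possible for the same reason. Of 256 alternative values for 34 results, 202 stayed within 1 SD (over autosomes, or over positions for depletion) or within 1.5 times the count, 53 moved further and 1 changed sign. Leaving out each chromosome in turn moved only long-range contacts and depletion beyond those limits. For slopes and correlations averaged over autosomes this outcome was fixed in advance. Dropping a single chromosome cannot shift such a mean by 1 SD over autosomes, so it gives no evidence that these results are stable. These alternatives are among the 202, so that count is in part set by construction. Without chromosome 3 chimpanzee had 0 long-range contacts, and without chromosome 4 gorilla had 0. The slope differences as results, low-signal bins left out, the deposited log scale, blocks not split at centromeres and the better matching of the first 2 components were chosen after seeing the data. Not run were the X chromosome, gene lists with their alternatives, and an eigenvector per chromosome, which needs contacts between blocks. A 5 Mb window gave no value at the chimpanzee position. Depth is unknown, so its limit could not be given. Where no reason is stated, the cause was not tested.

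Slopes fitted from 1 to 10 Mb were -1.03 in chimpanzee, -1.04 in bonobo and -1.05 in gorilla. Slope differences in that fit were 0.0108 for chimpanzee minus bonobo, turned from -0.0371, 0.0208 for chimpanzee minus gorilla and 0.00992 for bonobo minus gorilla. Similarity over pairs 2 to 10 Mb apart was 0.651 for chimpanzee with bonobo and 0.616 for chimpanzee with gorilla. Boundaries shared in the same bin were 54.2% for chimpanzee with bonobo, 46.6% for chimpanzee with gorilla and 45.1% for bonobo with gorilla, fewer by construction, and 78.8% for chimpanzee with gorilla within 2 bins. With 250 kb windows they were 79.8% for chimpanzee with gorilla and 79.3% for bonobo with gorilla, with 1 Mb windows 70.2% and 67.8%, and from observed over expected 68.9% for chimpanzee with gorilla. Boundaries numbered 3191 in chimpanzee and 3166 in bonobo with 250 kb windows, and 1284, 1206 and 1333 in chimpanzee, bonobo and gorilla with 1 Mb windows. Compartment bins of opposite sign that also differed by over 1 SD were 4.15%, 5.88% and 5.30% in the order of pairs above, fewer by construction.

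Divergent blocks in chimpanzee, bonobo and gorilla numbered 2882, 4344 and 4990 with 250 kb squares, 68, 190 and 184 with 1 Mb squares, 3353, 3448 and 5306 at a threshold of 0.5, 48, 253 and 168 at a threshold of 2, and 10582, 10447 and 11566 over all distances from 1 Mb up, where more blocks are tested or fewer pass by construction. Long-range contacts at 5 times or more numbered 416 in chimpanzee, 198 in bonobo and 121 in gorilla, and at 20 times 0 in chimpanzee and 0 in gorilla. The strongest depletion, as the difference to the nearer species on the log2 scale, was -0.86 in chimpanzee, -2.80 in bonobo and -2.40 in gorilla. It was -3.12 in bonobo and -3.27 in gorilla with 1 Mb windows, and -1.71 and -1.31 with 5 Mb windows. The strongest left was -0.66 in chimpanzee without chromosome 12, -2.52 in bonobo without chromosome 2 and -1.04 in gorilla without chromosome 1.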

Other observations

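Low-signal bins were more frequent in bonobo, with 274 bins (0.571%), than in chimpanzee, with 133 (0.277%), or gorilla, with 119 (0.248%). The stretches here were named after their values were seen. On chromosome 1 from 83.15 to 83.5 Mb the near-diagonal contact was 0.00759 of the chromosome median in bonobo, against 0.926 in chimpanzee and 0.839 in gorilla. On chromosome 22 from 18.15 to 19 Mb it was low in all 3 species, at 0.00062 in bonobo, 0.00324 in chimpanzee and 0.114 in gorilla.

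Of the tests below, the one leaving out block edges and depleted positions was set before its result was seen, and the others after. The tests of distant contacts, of a move, of the inversion and of noise were set again after values of earlier forms had been seen. The bonobo gap on chromosome 6 from 64.3 to 65.85 Mb was picked for its low near-diagonal contacts, so pairs inside it 250 kb or more apart were used, with a median observed over expected of 0.00196 in bonobo (95th percentile 0.0509, below the 5th percentile of each of the others), 1.24 in chimpanzee and 1.13 in gorilla. Sequence moved intact and still placed by the mapping would keep these contacts, so their near absence argues against such a move. These pairs lie in the bins picked for low contacts in a smoothed map, so they largely restate that pick. Contacts of the bins with bins over 5 Mb away in the same listed block, as observed over expected, stood at 0.117 of the block median in bonobo, against 1.05 in chimpanzee and 1.01 in gorilla. Low signal in these bonobo bins thus reached distant contacts as well. Under 0.1 was set to speak for bins without signal, so by that limit it stays open whether signal is wholly absent. Loss of all or part of the sequence from this line and sequence, moved or not, that the mapping could not place remain open too, as the 31 bins give no value that separates them. The gap was not even: the bonobo near-diagonal value rose to 0.210 of the chromosome median at 65 Mb, against 0 at 65.5 Mb. Some signal was thus placed inside it, and where that signal comes from was not tested. Apart from the move, no biological explanation of this gap was tested.

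On gorilla chromosome 1, contacts fell across 227.95 and 239.95 Mb, 12 Mb apart. Missing signal across these flanks is argued against by near-diagonal contacts of at least 1.02 times the chromosome median within 2 Mb, where 1 and 2 gorilla bins had low signal. An inversion between both positions would bring the 2 right flanks together and the 2 left flanks together: the right flanks stood at 1.97 in gorilla, above -1.81 in chimpanzee and -0.36 in bonobo, a gain at the 99.6th percentile of 249 blocks at that distance, but the left flanks gave a gain at the 55.4th percentile. At the left flanks gorilla stood at 0.44, above -0.56 in chimpanzee but not above 0.59 in bonobo. The gain over the higher of these was -0.15 (SD 0.386 over bin pairs), below the 0.46 of the 95th percentile. This argues against a simple inversion with both ends at these positions, although it rests on bonobo, and neighbouring pairs are not independent. Another arrangement of the gorilla sequence and errors in how positions were matched to hg38 stay open, untested. The best gains of the left flanks elsewhere in the block lay at the 85.7th and 71.4th percentiles of the best gains of 49 windows. In gorilla 218 to 218.25 Mb met 239.5 to 239.75 Mb at 5.50 times the expected value, beside 1.79 in chimpanzee and 1.15 in bonobo. That pair lies at the edge of the listed block, which starts at 218.05 Mb. In gorilla 223.75 to 224 Mb met 242.75 to 243 Mb at 6.74 times, beside 0.668 in chimpanzee and 0.864 in bonobo. This pair lies at the other edge of the block, which ends at 243 Mb. The hypothesis that gorilla chromosome 1 is arranged differently here may be followed up with the gorilla assembly.

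The closeness of the chimpanzee and bonobo maps at short range was set against 3 technical explanations. With low-signal bins left out the pair was the highest on 20 of 22 autosomes, and with bins near block edges and depleted positions left out too it was again the highest on 20, which argues against both as the whole cause, although the lead over the mean of the gorilla pairs fell from 0.0797 (SD 0.112) with all bins to 0.0510 (SD 0.0505) and then 0.0377 (SD 0.0372). More noise in the gorilla map could also lower its 2 correlations, although with low-signal bins left out the lead was 0.0510, 0.0519, 0.0529 and 0.0468 in bins of 50, 100, 250 and 500 kb, and adjacent pairs correlated at 0.938 in gorilla against 0.934 in chimpanzee and 0.926 in bonobo, values that smoothing also sets. The 250 and 500 kb bins hold pairs from 250 and 500 kb apart up, against 100 kb in the smaller bins, so these leads cover unlike distances. In 50 kb bins over 500 kb to 2 Mb, chimpanzee with bonobo averaged 0.827, chimpanzee with gorilla 0.776 and bonobo with gorilla 0.780. The lead in 500 kb bins exceeded the 0.0390 that noise alone would leave, if it shrank in step with 1 minus the correlation, by 0.00780 (SD 0.0145), above 0 on 16 of 22 autosomes but within its SD. That excess also mixes the change of bin size with the change of distances. The test therefore cannot decide, and noise cannot be told apart from a difference between the species. Shared descent of the 2 Pan species stays open and untested, since each species has 1 library.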
